A study of Mus musculus with 6 samples.

How the data were processed

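Gene expression was measured by RNA sequencing in mouse embryonic fibroblasts (MEF), primary connective tissue cells taken from embryos, here of the C57BL/6 strain and lacking p53. Per the labels, the 3 Control samples received no doxycycline and the 3 ONECUT3-OE samples received 100 ng/ml doxycycline, an antibiotic used here to switch on an inducible ONECUT3 gene. ONECUT3 belongs to the ONECUT family of cut-homeodomain transcription factors. Doxycycline was given to the ONECUT3-OE samples alone, so an effect of the antibiotic and an effect of ONECUT3 share one contrast. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

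Per the labels' protocols, total RNA was taken up in Trizol and purified on a silica column kit, and libraries were made with a kit that marks the strand of the RNA (NEBNext Ultra II Directional). The submitters' processing notes name HISAT2 with no version given, HTSeq 0.11.2 and DESeq2 1.26.0, and the builds GRCh38 and GRCm38, with no role for either build. Whether reads were counted by strand is not given in the sources used here. The deposited table gave whole-number read counts and FPKM for 27167 genes, with an Ensembl identifier and a symbol for each. Each of the 130132 FPKM values above 0 that the authors deposited implied a whole-number gene length when set against its count and the sum of its count column, and within each gene these lengths were equal (relative tolerance 1e-06). FPKM was 0 where the count was 0, so FPKM carried no information beyond the counts and a length. All 12 columns of values belonged to the 6 samples, and no row held anything other than a gene. Of the identifiers, 27156 were found in the GENCODE M21 annotation of GRCm38, which supplied the coordinates and gene types; 11 were not. The chromatin immunoprecipitation experiment that the study's design mentions was not analysed here.

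The column totals were 18265272, 16918605 and 18455452 counts in Control replicates 1, 2 and 3, and 19876539, 23107123 and 19718050 counts in ONECUT3-OE replicates 1, 2 and 3. All ONECUT3-OE libraries were thus deeper than all Control libraries. At this depth, 3 counts, the number that an observed count of 0 allows, are under 1 CPM (counts divided by library size in units of 1e+06 counts). Intervals on ratios of summed counts are exact binomial intervals at 95% and cover counting error only. Pairs of libraries were compared by a chi-square statistic over genes with at least 20 counts in the pair. It came to between 1.99 and 3.09 per degree of freedom within groups and between 23.4 and 26.8 across groups, so no pair agreed within sampling noise and each library was kept as 1 sample. The replicate numbers are shared by the groups, and the labels give them no further meaning.

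The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling and with genes kept by filterByExpr (minimum count of 10, minimum total of 15), which left 14242 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 are referred to as called, higher or lower in ONECUT3-OE, and log2 fold changes are ONECUT3-OE over Control. Standard errors (SE) are the log2 fold change divided by the square root of F. Levels are TMM-scaled CPM as mean ± SD over 3 libraries. The TMM factors lay between 0.9856 and 0.9902 in Control and between 1.011 and 1.013 in ONECUT3-OE.

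Before the data were examined, 58 lists of genes were written from textbook knowledge, among them markers of other cell types that a fibroblast culture could hold. The 53 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset inter-gene correlation of 0.01, both directions), with Benjamini-Hochberg adjustment over those 53. Camera with an estimated correlation and the rotation test fry, which asks whether a list's genes move on balance one way, served as alternatives. Members were also counted with their p-values adjusted over the list alone.

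The named genes follow a rule written before the data were examined. It takes Onecut1, Onecut2, Onecut3, Trp53, Cdkn1a and Mdm2. It takes the 12 largest rises and the 12 largest falls among called genes with a mean of at least 1 FPKM, no overlap between the groups and an established symbol. It takes up to 4 members of each fixed list with the smallest p among called members, or 2 members where none passed. Also taken are called genes of the ONECUT, neuronal transcription factor and liver lists changed at least 10-fold. Genes named outside this rule are said to have been chosen after their values were seen. For 237 named genes, the longest transcript was cut into stretches of 50 bases and these were sought in the transcripts of all other genes of GENCODE M21, and exon overlaps were measured. A gene with at least 25% of its stretches shared, or at least 25% of its exons overlapped on either strand, is treated as uncertain, since the counting could assign its reads elsewhere. This applied to 21 named genes.

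Alternatives fixed before the data were examined were DESeq2 1.42.0, DESeq2 size factors (RLE) or library totals within edgeR, no filter on low counts, a mean of at least 5 CPM, limma with an intensity trend on log2(FPKM + 1) and with pseudocounts of 0.1 and 0.01, each library left out in turn, the replicate number as a block, and a 2-fold minimum. Alternatives meant for a table without counts (limma without the trend, quantile normalization, median centring) did not apply. Chosen after seeing the data were random thinning of every library to the total of the smallest, removal of smooth trends on GC content and gene length through offsets, and a fixed dispersion of 0.01 with a likelihood ratio test.

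Both count tests were tested on simulated data drawn from the means, dispersions and library sizes of this comparison, with 200 genes changed by known folds, 50 of them at each fold. Over 14099 simulated genes, edgeR recovered 62% of genes changed 1.2-fold, 92% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold, and 4.32% of its calls were unchanged genes. DESeq2, over 14242 simulated genes, recovered 50%, 84%, 98% and 100% in the same order, with 0.599% of calls on unchanged genes. The changed genes were taken from those above a minimum mean level, so recovery of lower genes was not measured. Far fewer genes changed in the simulation than were called in the real comparison, so these shares need not hold there. Camera, over 14090 simulated genes, called 10 of 10 lists whose members all moved 1.2-fold and 0 of 40 unchanged lists; simulated genes were independent of each other, which genes of real lists are not.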

Results

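The transcriptomes of 6 samples of p53-null mouse embryonic fibroblasts were compared, 3 without doxycycline (Control) and 3 with doxycycline to induce the transcription factor ONECUT3 (ONECUT3-OE). Read counts per gene were available for 27167 genes, with column totals between 16918605 and 23107123 counts. The first principal component of the 6 profiles held 72.2% of the variance, and the other components held 7.8% or less each. The study asked which genes ONECUT3 regulates when it is induced, and the 1 comparison that the design offers is ONECUT3-OE against Control.

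Induction was visible in the counts. Onecut3 (ENSMUSG00000045518, chromosome 10, 80494835 to 80517276 on GRCm38) rose from 0.0365 ± 0.0633 CPM in Control to 5.93 ± 0.234 CPM in ONECUT3-OE (SD, n = 3 each). This rested on 2 counts over the Control libraries and 377 over the ONECUT3-OE libraries, a ratio of 157 with a 95% interval of 43.3 to 1300. Both Control counts came from replicate 3. Without that library the fitted log2 fold change of 7.07 became 9.87, which rests on a group at 0 counts and is no bound. The species of the introduced gene is not given in the sources used here, so reads on the mouse gene need not measure it in full. Onecut2 had a log2 fold change of 0.38 ± 0.30 (SE) and was not called (edgeR adjusted p = 0.312), and Onecut1 had 0 counts in Control and 2 in ONECUT3-OE, below the filter on low counts. Its count is uncertain, since 52.8% of its exons overlap Gm20649 on the same strand and 54.4% of its stretches occur in other genes.

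Trp53, the gene lacking by genotype in both groups, stood at 43.5 ± 0.976 CPM in Control and 48.7 ± 2.81 CPM in ONECUT3-OE. The labels do not say which part was removed, so counts over the whole gene do not check the deletion. The log2 fold change of 0.16 was called (edgeR adjusted p = 0.00425), but not without ONECUT3-OE replicate 1 (log2 fold change 0.12, adjusted p = 0.0579). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, fell by 0.70 on the log2 scale, from 5.58 ± 0.501 to 3.42 ± 0.260 CPM. Mdm2, whose product degrades p53, had a log2 fold change of 0.11 that lost its call when any of 4 libraries was left out (Control replicates 2 and 3 and ONECUT3-OE replicates 2 and 3, adjusted p between 0.0653 and 0.141).

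**Figure D1:**
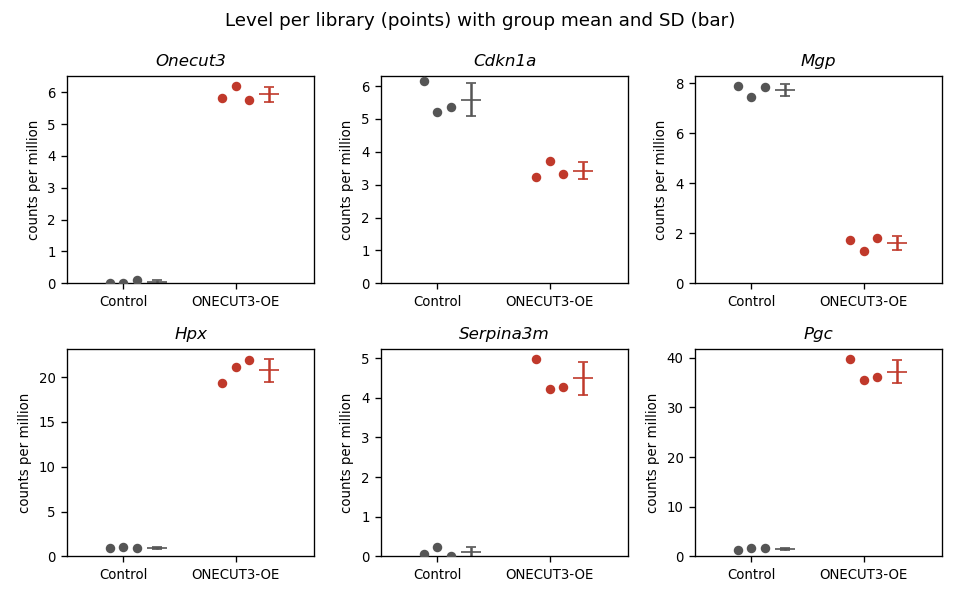
Levels of 6 genes in CPM (vertical axes, each from 0) in the 3 Control and 3 ONECUT3-OE libraries (points), with the group mean and SD (bars). Onecut3, Hpx, Serpina3m and Pgc were near 0 to 1.53 CPM on average in Control and at 4.49 to 37.2 CPM in ONECUT3-OE, while Cdkn1a and Mgp were lower in all 3 ONECUT3-OE libraries.

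Among called genes with a mean of at least 1 FPKM, no overlap between the groups and an established symbol, the 12 largest rises started from Control means of 2.91 CPM (Thbs4) or less. Pgc, the precursor of the stomach protease gastricsin (chromosome 17, 47726842 to 47734482), went from 1.53 ± 0.224 to 37.2 ± 2.32 CPM, a 24.2-fold rise. Hpx, the plasma heme-binding protein hemopexin (chromosome 7, 105591613 to 105600137), rose 22.3-fold to 20.8 ± 1.31 CPM, and Kcnn4, a calcium-activated potassium channel, 21.6-fold to 13.2 ± 0.594 CPM. Serpina3m and Wfdc18 had 5 Control counts each against 284 and 196 in ONECUT3-OE, ratios of 47.4 (95% interval 20.1 to 147) and 32.7 (13.8 to 102). Log2 fold changes between 2.69 and 3.39 were fitted for Prg4, which encodes the joint lubricant lubricin, the skin barrier genes Lce1g and Sprr2g, the protease inhibitor Serpinb1a, the nociceptin receptor Oprl1, the GDNF co-receptor Gfra1 and the matrix protein Thbs4. Sprr2g is annotated as a polymorphic pseudogene.

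Under the same filter, the 12 largest falls started from Control means between 2.28 CPM (Sprr1a) and 86.7 CPM (Angptl7). The chemokine gene Cxcl13, below the filter and named after its values were seen, fell by 5.06 on the log2 scale, more than any of these 12. Angptl7, a secreted angiopoietin-like protein (chromosome 4, 148495183 to 148500460), fell from 86.7 ± 1.92 to 6.94 ± 0.421 CPM, 12.5-fold lower. Hpgd, which inactivates prostaglandins, and the matrix protease Mmp10 fell by 3.24 and 2.83 on the log2 scale. Arc, an activity-regulated gene, the angiopoietin Angpt4 and Mgp, an inhibitor of calcification, fell by 2.79, 2.70 and 2.27. The keratinocyte genes Cdsn, Sprr1a and Ivl fell by 2.65, 2.57 and 2.44 and Krt15 went from 4.26 ± 0.398 to 1.06 ± 0.147 CPM, while Lce1g and Sprr2g of the same tissue program rose. Nkd1, a WNT antagonist, went from 36.5 ± 1.17 to 8.81 ± 0.705 CPM and Spon2, a matrix protein gene with 76.3 ± 3.04 CPM in Control, fell by 2.01 on the log2 scale.

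**Figure D2:**
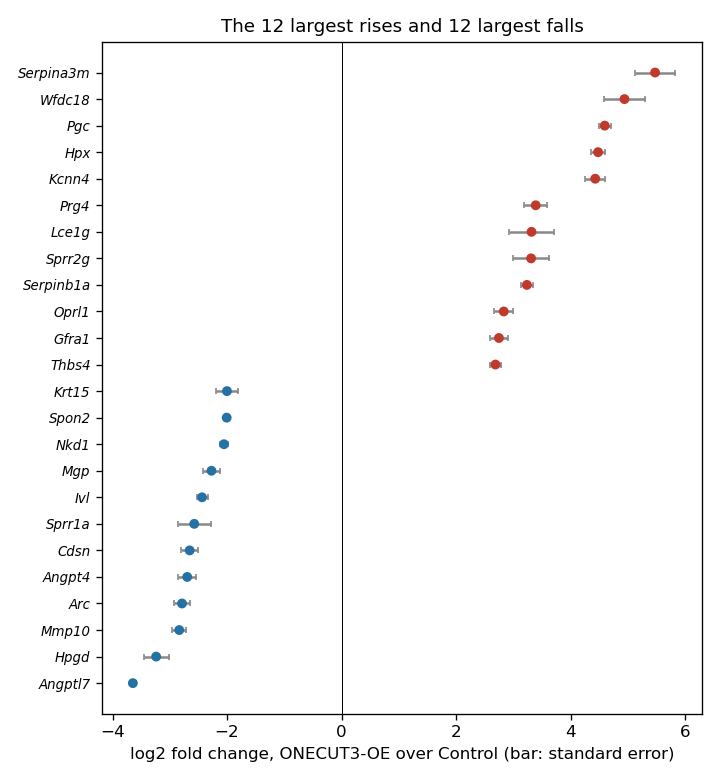
Fitted log2 fold change (horizontal axis, ONECUT3-OE over Control) with its standard error (bars) for the 12 largest rises and 12 largest falls taken by the fixed rule. The rises span 2.69 (Thbs4) to 5.48 (Serpina3m) and the falls reach -3.64 (Angptl7).

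Over all genes, 6534 of 14242 tested were called, 3214 higher and 3320 lower, with 7430 at an unadjusted p under 0.05. Most shifts were small. The median absolute log2 fold change of called genes was 0.258, and 80.2% of them changed less than 1.5-fold. At least 2-fold changes were called for 180 genes higher and 366 lower, and at least 10-fold changes for 26 higher and 2 lower. The groups did not overlap in 52.1% of tested genes, where chance gives 10%. The biological coefficient of variation between replicates was 2.37%, and with 10% assumed instead (a fixed dispersion of 0.01) 2158 genes were called. The split of higher and lower calls depended on scaling: on log2(FPKM + 1), which is scaled by column totals, 59.4% of calls were higher, against 49.2% in the main test.

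Of the 53 fixed lists tested, 23 were called by camera, 7 higher and 16 lower, and 5 of these held with an estimated correlation: mitosis, cholesterol biosynthesis, matrix proteases, complement and acute phase, and mesothelial markers, each at adjusted p = 0.0380 with an estimated correlation. The other 18 camera calls were lost with an estimated correlation. That form of the test differs from the preset one in more than the correlation. With it, the WNT and integrin lists lost their call at estimates of 0.00771 and -0.00377, below the preset 0.01. All 23 lists were also called by fry in the same direction, although fry does not compare a list with other genes.

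Genes of cell division rose as groups by small amounts. All 39 tested mitosis genes were higher, with a median log2 fold change of 0.324 (camera adjusted p = 8.24e-16). Cdc20, an activator of the anaphase-promoting complex, rose by 0.48, the mitotic kinesin gene Kif20a by 0.46 (uncertain, since 29.3% of its exons overlap Cdc23 on the other strand), the cell cycle transcription factor gene Foxm1 by 0.43 and the cyclin gene Ccna2 by 0.37. Of 44 DNA replication genes, 34 were higher and 1 lower, among them Rrm2 (0.60), Mcm5 (0.47), Tyms (0.33) and Pcna (0.30, uncertain, with 31.8% of its stretches in a pseudogene). The list was called at camera adjusted p = 1.85e-07, and had adjusted p = 0.0733 with an estimated correlation. MYC target and ribosome biogenesis genes had 24 higher and 1 lower of 35 (adjusted p = 0.00327, and adjusted p = 0.244 with an estimated correlation), with Utp20, Ddx21, Cad and Bop1 at 0.23 to 0.29. The list of cyclins and cell cycle inhibitors was not called (10 higher, 3 lower of 20, adjusted p = 0.130): Ccnd2 and Cdk6 rose by 0.31 and 0.43, the inhibitor gene Cdkn2c rose by 0.42 and the inhibitor gene Cdkn2b fell by 0.56.

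Cholesterol biosynthesis and uptake genes were higher in 23 of 24 members, with none lower (median 0.277, camera adjusted p = 5.67e-08). Tm7sf2, a sterol reductase gene, had the largest rise, from 5.89 ± 0.350 to 21.7 ± 0.332 CPM. Sqle, Insig1 and Hmgcs1 rose by 0.43, 0.45 and 0.27 on the log2 scale. Fatty acid synthesis genes were not called as a list (6 higher, 2 lower of 15), with Srebf1, Elovl6 and Fasn higher and the desaturase gene Fads2 lower.

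Mitochondrial lists shifted by smaller amounts. Nuclear-encoded respiratory chain genes had 56 of 76 members higher and 1 lower (median 0.126, camera adjusted p = 1.09e-04, and adjusted p = 0.669 with an estimated correlation), among them the ATP synthase genes Atp5b, Atp5g3, Atp5j2 and Atp5k at 0.21 to 0.26. Mitochondrial ribosomal protein genes had 31 higher and 2 lower of 76 (median 0.101, adjusted p = 0.0159, and adjusted p = 0.710 with an estimated correlation), with Mrpl48 at 0.43 and Mrpl11 at 0.26. Removal of trends on GC content and gene length ended this call (adjusted p = 0.116); the list median less that of all tested genes went from 0.0964 to 0.0721. Genes encoded by mitochondrial DNA had 2 higher and 3 lower of 10 and cytosolic ribosomal protein genes 11 higher and 8 lower of 78, and neither list was called. mt-Atp6 (uncertain, with 99.5% of its stretches in other genes) was 1 of the called members only because of ONECUT3-OE replicate 2: without that library its log2 fold change of 1.10 was 0.23 (edgeR adjusted p = 0.534).

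Interferon-stimulated genes were higher in 23 and lower in 3 of 43 members (median 0.241, camera adjusted p = 0.00823, and adjusted p = 0.168 with an estimated correlation). The antiviral gene Ifit1 rose by 0.76, Rtp4 by 1.02 and the GTPase gene Irgm1 by 0.42, while Bst2, which encodes tetherin, fell by 0.41. Antigen presentation genes were not called as a list (3 higher, 6 lower of 17), and H2-T23, H2-K1 and Tap2 were lower by 0.88, 0.36 and 0.40.

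Most tested members of the matrix lists were called lower. Of 35 fibrillar collagens and matrix glycoproteins, 24 were lower and 7 higher (median -0.349, camera adjusted p = 5.30e-11, and adjusted p = 0.0733 with an estimated correlation). Fn1, which encodes fibronectin, went from 16480 ± 205 to 8976 ± 67.3 CPM, a log2 fold change of -0.88 ± 0.022 (SE, edgeR adjusted p = 7.0e-28). Thbs2, Fbln2 and Dcn fell by 0.75, 0.66 and 0.60. Basement membrane genes were lower in 12 and higher in 3 of 20 (adjusted p = 8.30e-08, and adjusted p = 0.112 with an estimated correlation), with Col15a1 down by 1.86, the nidogen gene Nid2 by 1.21 and the laminin genes Lamb1 and Lama5 by 0.59 and 0.47. Matrix proteases and their inhibitors were lower in 20 and higher in 4 of 31 (median -0.292, adjusted p = 5.46e-11). Mmp3, at 90.4 ± 1.11 CPM in Control, fell by 1.42, and Adamts2 and Adamts5 fell by 0.92 and 0.86. Integrins and adhesion receptors were lower in 18 and higher in 8 of 34 (adjusted p = 0.00823, and adjusted p = 0.118 with an estimated correlation), with Alcam down from 536 ± 4.71 to 217 ± 5.74 CPM, the integrin genes Itga11 and Itga3 down by 1.22 and 0.80 and Nrp1 up by 0.94. The call was lost on log2(FPKM + 1) (adjusted p = 0.0539).

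Complement and acute phase genes were lower in 12 and higher in 3 of 21 (median -0.272, camera adjusted p = 2.38e-09). C3, the central complement component, fell from 907 ± 5.69 to 285 ± 3.13 CPM (edgeR adjusted p = 2.8e-34), the acute phase gene Saa3 from 1380 ± 45.1 to 803 ± 16.9 CPM, and Cd55 and Steap4 by 0.89 and 0.78 on the log2 scale. At least 2-fold changes were called for 2 members higher and 3 lower. The 2 higher, Serpina3n and Serpina3g, were chosen after their values were seen and rose by 2.55 and 1.02. Cytokine and chemokine genes were not called as a list (8 higher, 9 lower of 27), with Cxcl5 up by 1.42, Cxcl12 down by 0.78 and Ptgs2 down by 0.68. NF-kB targets also went both ways (6 higher, 4 lower of 19), Tnfaip2 falling by 0.98 and Cxcl1, Nfkb1 and Vcam1 rising by 0.51, 0.50 and 0.37.

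By camera, the immediate early, ERK, YAP and TEAD and TGF-beta lists were called lower with the preset correlation but not with an estimated one. With fry, which does not compare a list with other genes, all of them were lower too (fry adjusted p between 3.32e-04 and 6.77e-04). These lists share members, such as Ier3 in the immediate early and ERK lists and Ctgf in the YAP and TGF-beta lists. Immediate early and AP-1 genes were lower in 19 and higher in 1 of 24 (median -0.430, camera adjusted p = 6.53e-09, and adjusted p = 0.136 with an estimated correlation). Egr1, Fos and Fosb fell by 0.90, 0.79 and 0.80, and Klf4 was the member that rose, by 0.99. ERK pathway outputs were lower in 15 and higher in 5 of 22 (adjusted p = 0.00891, and adjusted p = 0.264 with an estimated correlation), with Ier3, Epha4 and the phosphatase gene Dusp6 down by 0.55, 0.63 and 0.53. YAP and TEAD targets were lower in 16 and higher in 3 of 26 (adjusted p = 0.00301, and adjusted p = 0.168 with an estimated correlation), with Ctgf, Cyr61, Dock5 and Fgf2 down by 0.29 to 0.59. TGF-beta response genes were lower in 16 and higher in 3 of 27 (adjusted p = 0.00301, and adjusted p = 0.301 with an estimated correlation). Tgfbi fell by 1.23, whereas Inhba, an activin subunit gene, and Id2 rose by 0.86 and 0.76.

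WNT pathway genes were lower in 20 and higher in 9 of 36 (median -0.317, camera adjusted p = 0.00185, and adjusted p = 0.112 with an estimated correlation). Nkd1 and the secreted inhibitor gene Sfrp1 fell by 2.05 and 1.15, while the receptor gene Lgr4 and Sfrp2, an inhibitor of the same family as Sfrp1, rose by 1.02 and 1.09. Insulin-like growth factor genes were lower in 12 and higher in 3 of 17 (adjusted p = 5.67e-08, and adjusted p = 0.0844 with an estimated correlation). The binding protein genes Igfbp2, Igfbp4 and Igfbp6 fell by 1.95, 1.17 and 0.47. Angiogenesis ligands and guidance genes were lower in 21 and higher in 9 of 36 (adjusted p = 8.24e-04, and adjusted p = 0.257 with an estimated correlation), with Sema3c down from 1217 ± 22.2 to 531 ± 8.17 CPM, Efnb2 and Sema3f down by 0.71 and 0.66 and Slit2 up by 0.57. The lists of NOTCH (6 higher, 2 lower of 14), Hedgehog (2 higher, 4 lower of 10) and BMP genes (6 higher, 11 lower of 21) were not called. Within them the NOTCH ligand gene Jag1 rose by 1.19 and Jag2 fell by 1.46, Smo and Gli2 rose by 0.59 and 0.65, and the BMP antagonist gene Chrd and Bmp4 fell by 1.73 and 0.65.

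Hypoxia response genes were lower in 16 and higher in 1 of 22 (median -0.300, camera adjusted p = 1.04e-07, and adjusted p = 0.0733 with an estimated correlation). Car12, a carbonic anhydrase gene, Ak4 and Bnip3 fell by 1.55, 1.36 and 0.84, and the collagen prolyl hydroxylase gene P4ha1 by 0.44. Glycolysis genes were lower in 15 and higher in 2 of 22 (adjusted p = 8.24e-04, and adjusted p = 0.206 with an estimated correlation), with the lactate transporter gene Slc16a3 down by 0.51 and Pfkp, Pfkfb3 and Pfkl down by 0.34 to 0.56.

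**Figure D3:**
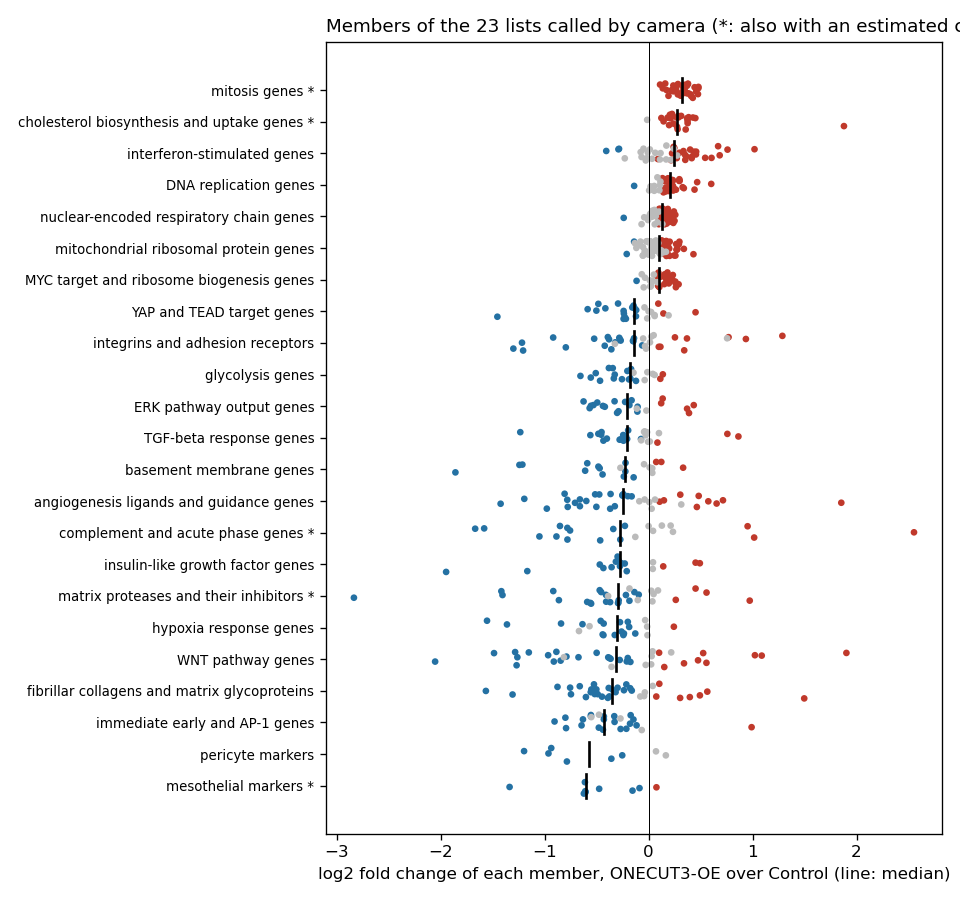
Log2 fold change of each tested member (points; red called higher, blue called lower, grey not called) of the 23 lists called by camera, with the list median (black lines); asterisks mark the 5 lists that also held with an estimated correlation. Medians run from -0.606 (mesothelial markers) to 0.324 (mitosis genes).

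Among markers of other cell types, the mesothelial and pericyte lists were called, both lower. Of 9 mesothelial markers, 8 were lower and 1 higher (median -0.606, camera adjusted p = 1.97e-10), and several stood at high levels in all libraries: Wt1 went from 429 ± 3.03 to 309 ± 2.94 CPM, Gpm6a from 314 ± 10.7 to 205 ± 5.85, Bnc1 from 164 ± 8.04 to 106 ± 2.30 and Muc16 from 65.4 ± 3.47 to 25.9 ± 3.40. Pericyte markers were lower in 6 and higher in 0 of 8 (adjusted p = 0.00908, and adjusted p = 0.197 with an estimated correlation), with Notch3 down by 0.96, Mcam by 0.36 and Pdgfrb by 0.25 and Anpep at 4.99 ± 0.707 CPM in Control and 2.19 ± 0.277 in ONECUT3-OE. These falls accompany those of the matrix, complement and adhesion lists above. Epithelial markers went both ways (6 higher, 7 lower of 17, adjusted p = 0.0806), with Krt7, Krt14, Dsp and Krt19 down by 1.43, 1.08, 0.74 and 0.61. Endothelial markers (0 higher, 3 lower of 6, with Kdr and Egfl7 down by 1.02 and 1.01), neural crest and glial markers (1 higher, 2 lower of 6), skeletal muscle genes (2 higher, 0 lower of 7), smooth muscle and myofibroblast genes (5 higher, 5 lower of 17), chondrocyte and osteoblast genes (4 higher, 3 lower of 16) and adipocyte genes (1 higher, 6 lower of 11) were not called as lists. Acta2, the smooth muscle actin gene, rose by 0.48 while Mylk and Des fell by 1.45 and 1.08; the cartilage regulator genes Sox9 and Sox6 rose by 1.23 and 1.69. The muscle myosin gene Myh1 had 3 Control counts against 87, a ratio of 24.2 (95% interval 8.02 to 120), and is uncertain because 26.7% of its stretches occur in other myosin genes.

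Of the lists for tissues in which ONECUT factors are known to act, the 2 with enough tested members were not called by camera. Liver-enriched transcription factors and hepatocyte genes had 2 higher and 2 lower of 8 tested members (camera adjusted p = 0.944). The counts held 23 genes of this list, and the others fell below the filter on low counts. Among the untested genes, Alb had 3 Control counts against 22 and Nr5a2 had 13 against 2. The result for the list thus does not cover genes with few or no counts. Cps1, the first enzyme of the urea cycle and the 1 gene of this list changed at least 10-fold, had 3 Control counts against 65 (ratio 18.1, 95% interval 5.92 to 90.0), Krt8 was higher by 0.46 (uncertain, with 26.9% of its stretches in a pseudogene) and Cebpa lower by 0.53. Neuronal cytoskeleton and synapse genes had 9 higher and 4 lower of 24 tested members (camera adjusted p = 0.435). The counts held 35 genes of this list, and the others fell below the same filter. The tested neuronal members were higher on balance with fry (adjusted p = 0.0206), which does not compare a list with other genes. That call is not particular to this list, since fry called 39 lists, 16 of them not called by camera. Uchl1, Elavl2 and the neurofilament gene Nefl were higher by 0.72, 0.73 and 3.88 and Kif1a was lower by 0.73. Nefl is uncertain, since 32.8% of its exons overlap Nefm on the other strand. The 5 lists with fewer than 5 tested members were not tested as groups in the main test. Among them, 3 of 4 tested neuronal transcription factors were higher (Sox11 by 0.70, Ebf1 by 0.40 and Tfap2a by 0.60, the last not called without Control replicate 2, adjusted p = 0.0652), 1 of 2 ONECUT genes was higher, 1 of 3 endocrine pancreas genes was lower, 2 macrophage markers were higher and 1 lower of 4, and 1 erythroid gene was not called. With any 1 Control library left out, 5 neuronal transcription factors were tested and the list was called higher (camera adjusted p between 0.0233 and 0.0331). With any ONECUT3-OE library left out, the list again had fewer than 5 tested members, so the call hangs on which members pass the filter. The list was not called with no filter on low counts (21 tested, camera adjusted p = 0.121). Mrc1, among those macrophage markers, had 4 Control counts against 110.

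The remaining lists went both ways or stayed below the threshold. Canonical p53 targets had 8 higher and 8 lower of 28 (camera adjusted p = 0.931), with the death receptor gene Fas up by 0.81, Gtse1 up by 0.44, and Pmaip1 and Plk2 down by 0.56 and 0.26. Apoptosis regulators had 10 higher and 4 lower of 27, with Bmf down by 1.51. Genes of the ATF4-driven stress response had 8 higher and 14 lower of 31 (adjusted p = 0.558), with Psat1 and Mthfd2 up by 0.32 and 0.36 and Aldh18a1 and Pck2 down by 0.28 and 0.27. Genes of the unfolded protein response had 6 higher and 6 lower of 25, cytosolic heat shock genes 4 and 4 of 16, and NRF2 targets 11 and 6 of 26, with Gsta4 up by 0.97. Autophagy and lysosome genes had 4 higher and 10 lower of 30, with Gpnmb up from 31.4 ± 1.90 to 132 ± 1.37 CPM and Ctsl down by 0.66 (uncertain, with 26.8% of its exons overlapped on the other strand). Replication-dependent histone genes (1 higher, 3 lower of 10), Hox genes (7 higher, 1 lower of 28), mesenchymal transition genes (5 higher, 8 lower of 19, with Vim up by 0.27 and Pdgfra down by 0.44) and stem cell markers (4 higher, 3 lower of 12) were not called.

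Adjusted over the list alone, the counts of called members were the same as over all genes in 14 of the 23 called lists. The other 9 gained 1 or 2 members, among them immediate early genes (21 lower), DNA replication genes (36 higher), respiratory chain genes (57 higher), fibrillar matrix genes (25 lower) and matrix proteases (5 higher, 21 lower). Adjusted over the list alone, smooth muscle genes had 9 lower, cytosolic heat shock genes 8 higher, and cytosolic ribosomal protein genes 7 higher and 4 lower.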

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

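The thinning, the GC content and length correction and the fixed dispersion were chosen after seeing the data; the other settings were chosen before. Onecut3 kept its direction and its call in every setting run, except a mean of at least 5 CPM, which left it untested, with log2 fold changes between 6.54 and 9.87 when each library was left out; values on log2(FPKM + 1), such as 1.16, are compressed by the pseudocount. The number of genes called between ONECUT3-OE and Control (6534) was 4661 with DESeq2, 6526 with DESeq2 size factors, 6898 with library totals, 6409 with no filter, 5693 with a mean of at least 5 CPM, 6237 on log2(FPKM + 1), 6339 after thinning, 6664 after the GC content and length correction, and between 5728 and 6376 when each library was left out. Of the 6534 genes, 4639 remained called with DESeq2 and 6139 after thinning, and no gene that remained called changed sign in any setting run. With library totals 59.0% of calls were higher and with the GC content and length correction 40.6%, against 49.2% in the main test.

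A 2-fold minimum left 546 genes, 180 higher and 366 lower, by its own construction. The fixed dispersion of 0.01, which sets 10% variation between replicates, left 2158 genes, 715 higher and 1443 lower; the assumed spread is larger than the measured one, and most called changes are small.

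The number of fixed gene lists called (23, with 7 higher and 16 lower) fell to 5, with 2 higher and 3 lower, with an estimated correlation, and was 39, with 13 higher and 26 lower, with fry, which does not compare a list with other genes. All 23 lists kept their call and direction with fry, with DESeq2, with other scaling and with no filter. They also kept both after thinning and when any library was left out (23 to 24 lists called). The call was lost by integrins and adhesion receptors on log2(FPKM + 1) (adjusted p = 0.0539) and on log2(FPKM + 0.1) (0.0506), and by mitochondrial ribosomal protein genes after the GC content and length correction (0.116). With a mean of at least 5 CPM the pericyte list had fewer than 5 tested members and the other 22 lists kept their call. Calls were gained by cyclins and cell cycle inhibitors (0.0276) and BMP genes (0.0365) with no filter, by BMP genes with DESeq2 (0.0335) and by epithelial markers with a mean of at least 5 CPM (0.0347); the cause was not tested. Neuronal and neural progenitor transcription factors, with too few tested members in the main test, were called higher when any Control library was left out (5 tested, adjusted p between 0.0233 and 0.0331), but not with no filter (0.121) or DESeq2 (0.168), which tested 21. When any ONECUT3-OE library was left out, the list again had too few tested members. For lists and named genes called neither in the main test nor in the alternative, the direction turned in 42 combinations with a setting, fry among these settings.

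Of 233 called named genes other than Onecut3, 12 lost their call in at least 1 setting besides the fixed dispersion (Egr2, Fabp7, Gck, Hist1h2ac, Mdm2, mt-Atp6, mt-Cytb, Myh8, Rpl23, Rpl27, Tfap2a and Trp53; mt-Atp6, Rpl23 and Rpl27 are uncertain for shared stretches), 54 lost it with the fixed dispersion, and 0 changed sign.

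The counts gave no sign that the replicate numbers pair the samples. Deviations from the group means correlated at -0.15, 0.044 and -0.05 between samples of the same number, and not every sample correlated best with its own number. With 3 libraries per group, these correlations cannot exclude pairing. With the replicate block 6346 genes and the same 23 lists were called, and the block changed the call of no named gene.

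Depth limits low genes, and ratios for genes with up to 5 Control counts carry wide intervals.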

Other observations

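The tests in this part were chosen after the results were seen, except the counts over other splits of the samples. Several genes outside the fixed rule, chosen after their values were seen, went from a few reads to more reads in ONECUT3-OE. The rising genes given here had means between 0.131 (Ret) and 0.508 FPKM (Chodl), below the 1 FPKM of the rule. Chodl, a lectin gene, had 5 counts over the Control libraries and 343 over the ONECUT3-OE libraries, Ace2, which encodes a carboxypeptidase, 4 and 163, and Acsm3 2 and 113. Cux2, a cut-homeodomain transcription factor gene related to the ONECUT family, had 4 and 203. Ret, which encodes the receptor tyrosine kinase that signals with Gfra1, had 10 and 99. Transcripts of both parts of this GDNF receptor were thus higher (Gfra1 by 2.75 on the log2 scale), with Ret still low at 1.56 ± 0.221 CPM in ONECUT3-OE. The chemokine gene Cxcl13 went the other way, with 67 Control counts and 2 in ONECUT3-OE.

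Several neighbours of Serpina3m in the protease inhibitor cluster on chromosome 12 were higher too. Serpina3n rose by 2.55, Serpina3h, annotated as a transcribed pseudogene, by 1.53 and Serpina3g by 1.02 on the log2 scale. Of the stretches of Serpina3m, 19.1% occur in other Serpina3 genes. On chromosome 15, Col14a1 went from 7.23 ± 0.529 to 20.4 ± 1.33 CPM, and the predicted genes Gm18787 and Gm49257, which lie inside it on the other strand, had 2 and 1 Control counts against 114 and 42.

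Xist, transcribed from the inactive X chromosome, had between 11450 and 14325 counts in every library, and the 4 Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty together between 343 and 503. Xist fell by 0.24 on the log2 scale, while none of these 4 Y-linked genes was called.

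Other splits of the 6 libraries into 3 and 3 were fitted in the same way. Of 10 splits, the real one called 6534 genes and the highest of the others 0; for lists the real split called 23 and the highest of the others 19. Each of the other splits keeps 2 libraries of one group on each side, so part of the group difference stays in them. As 10 splits cannot give a share under 0.05, 1 split with a count as large (the real one) decides nothing.

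For the joint shift of many lists, the larger number of counts in ONECUT3-OE is argued against. All 23 lists kept their call after thinning to equal depth. Thinning keeps relative levels, so a difference in preparation that went with depth would remain, and it was not tested. GC content and gene length are argued against for 22 lists, which kept their call after correction. The mitochondrial ribosomal list did not (adjusted p = 0.116): its median less that of all tested genes went from 0.0964 to 0.0721 (SD of its 76 members 0.12 before and 0.121 after), so a part of its shift went with the trends and its source stays open. Doxycycline can disturb mitochondrial translation, and a stress response to that may raise ATF4 targets. That list went both ways (8 higher, 14 lower): it was lower on balance with fry (adjusted p = 0.0156) and not called by camera (adjusted p = 0.558), while Psat1 and the mitochondrial one-carbon gene Mthfd2, its members with the smallest p, rose by 0.32 and 0.36 on the log2 scale, so this stays open. Another effect of doxycycline cannot be told apart from ONECUT3, because 0 libraries had the antibiotic without the induced gene.

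Mesothelial markers were lower, which could come from a smaller share of mesothelial cells in ONECUT3-OE. If no other cells expressed them, that would lower the markers by a common factor. Yet Muc16 fell by 1.34 on the log2 scale, Upk3b and Lrrn4 by 0.15 and 0.09, and Upk1b rose by 0.08 at 265 CPM in Control (Cochran's Q of 897 over 9 markers). A change in the share of cells that alone express all 9 markers is thus argued against. Expression of the markers in the other cells was not measured and would make the falls unequal. A change in share therefore stays open, as does a change in the expression of these genes.

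Of the 13 protein-coding genes of mitochondrial DNA, 6 had at most 119 counts in any library (mt-Nd3, mt-Nd4l, mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8) while the other 7 had at least 2099. A candidate explanation is that reads matching nuclear copies as well were dropped. Between 98% and 100% of the stretches of 5 of the 6 occur in other annotated transcripts, and at most 62.2% of those of the other 7 (Fisher's exact test, two-sided, p = 0.00466); mt-Atp8, at 0%, is the exception. If so, the values of the 5 genes with at least 98% of their stretches shared, mt-Atp6 included, say little about mitochondrial transcription. The cause of the low counts of mt-Atp8 was not tested.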
